A study of Homo sapiens with 3 samples.

How the data were processed

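Binding of 3 purified full-length human proteins to synthetic DNA was measured on custom microarrays, with 1 array per protein. The proteins were HOXC11 (His tag), P53 (GST tag) and POU6F1 (His tag); the labels give E. coli as their source and Alexa647 as the dye. Each array held 19392 hairpin spots and 858 control spots. The hairpins comprised 522 different sequences, of which 442 had 32 spots, 76 had 64 and 4 had 96. In each hairpin the first arm carried the binding site (the top strand), a short loop followed, and the complementary arm carried the bottom strand. The letter X in the deposited sequences always stood opposite G and was read as 5-methylcytosine (5mC), the modified base that the study's design describes. Positions are counted from 1 at the 5′ end of the varied region on the top strand, and a methylated cytosine of the bottom strand has the position of the top base opposite it.

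The spot intensity that the authors deposited is the median pixel value at 635 nm after a local scaling, without subtraction of the local background. The scaling was worked out from the values: for 19392 of 19392 hairpin spots on each array, the scaled intensity equalled the raw spot median times the array median, divided by the median of the 9 by 9 spots around it. The scaling factors ran from 0.431 to 3.73 on the HOXC11 array, from 0.616 to 26.9 on the P53 array and from 0.766 to 3.07 on the POU6F1 array. The percent of saturated pixels per spot is given per the file headers, and 87, 36 and 2 hairpin spots had any on the HOXC11, P53 and POU6F1 arrays. The software of spot extraction and its version were not given in the sources used here.

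The authors' scaled intensities were taken to log2 and averaged over the spots of each sequence, whatever names the sequence had. Differences between sequences were tested with limma 3.58.1 in R 4.3.3: spot variances per sequence were shrunk with squeezeVar, degrees of freedom followed Satterthwaite, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the contrasts of 1 kind on 1 array. A contrast was called at an adjusted p under 0.05. A contrast was tested only where a sequence in it was brighter than the 95th percentile of 30 random sequences on that array, of which 14 carried 5mC and 16 did not. Where a reference lay below that level, a substitution could be tested only if it was brighter. In all, 198 single-base substitutions, 90 contrasts with a single 5mC outside CpG, 176 contrasts of CpG methylation (top strand only, bottom strand only or both strands) and 56 departures from additivity of the 2 strands could be formed. The departure was the log2 signal of the fully methylated CpG minus that of each hemimethylated state plus that of the unmethylated state. Differences of methylation effects between arrays were tested in the same way, with variances kept separate per array. Correlations used 100000 permutations, and comparisons with fewer than 10 sequences in a group used exact permutation. The difference between the correlations at CpG positions and at other positions used 10000 permutations. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.

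There was 1 array per protein. Spots are technical replicates, so the standard errors and p-values cover the spread between spots of 1 array and not the spread between experiments, and protein, tag, supplier and array cannot be told apart. The number of arrays limits the precision. The median spot SD per sequence was 0.18 log2 units on the HOXC11 array, 0.27 on the P53 array and 0.14 on the POU6F1 array. Since the local background is part of every intensity, folds near the level of the random sequences are understated, most of all on the POU6F1 array.

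The groups, tests, detection rule, motif classes, the rule for naming contrasts and most alternatives were fixed before the data were examined. Named were, per array and kind, up to 4 called contrasts with the largest rise and 4 with the largest fall, at most 2 per site and direction, with the 3 brightest reference sites per array and the 3 largest departures from additivity. Each array's own sites were summarised by count, with the largest rise and fall. Alternatives fixed then were no detection rule, the 99th percentile as threshold, spot medians without spots over 3 median absolute deviations away, a permutation test of the spots, a variance prior with an intensity trend, removal of a residual spatial trend, the spot mean column, odd-ordered and even-ordered spots, saturated spots left out, and a change of at least 1.5-fold. The unscaled spot medians, separate spots for the unmethylated sequence in each effect, own sites only, detection from the random sequences without 5mC, and separate spots within and outside CpG were chosen after seeing the data. The rank correlation with separate spots is not reported here. The values of the series matrix equalled the scaled intensities within 0.001 for 19392 spots on each array and gave no other result. Methylation combinations at several CpGs and 5mC in flanks were not analysed here, because no such sequences were found. An array without protein was not used here.

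The pipeline was tested on simulated data, in which shifts were added to spots drawn with each array's own variances. All shifts of 1 log2 unit were recovered, 100% in every kind on every array. For shifts of 0.25 the lowest share recovered was 54.7%, in the departures from additivity on the P53 array. The share of calls that were false was lowest, 2.8%, for 5mC outside CpG on the HOXC11 array and highest, 10.3%, for the substitutions on the POU6F1 array, which is above the nominal level of 5%. As a check on the spots, 80 sequences present under more than 1 name were compared between names: an unadjusted p under 0.05 was found for 1, 2 and 2 of them on the HOXC11, P53 and POU6F1 arrays, and for 0 after adjustment on each.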

Results

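The signal of 3 fluorescently labelled transcription factors was measured over 6 binding sites, their single-base variants and their cytosine-methylated forms, with 1 array each for HOXC11, P53 and POU6F1. The sites were a pair for HOXC11, a pair for POU6F1, and a p53 site and a p63 site that counted as the sites of P53. Every sequence had at least 32 spots, and 30 random sequences served as background, of which 14 carried 5mC. The median raw intensity was 9096 on the HOXC11 array, 4031.5 on the P53 array and 347 on the POU6F1 array, against a median local background of 3355, 1064 and 291. The raw signal lay above the local background in 99.8%, 95.3% and 75.7% of the hairpin spots. There were no replicate arrays, and n below counts spots.

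P53 and POU6F1 gave more signal on both of their own sites than on any random sequence, and HOXC11 did not. On the P53 array the p53 site CATGCCCGGGCA reached a mean log2 signal of 14.45 ± 0.52 (SD, n = 64), 6.52-fold above the median random sequence, and the p63 site CACGTGGTGGCA reached 12.95 ± 0.23 (SD, n = 64), 2.31-fold above it. On the POU6F1 array site 1, ATAATGAGGT, reached 11.41 ± 0.34 (SD, n = 64), 8.57-fold above the median random sequence, and site 2, ATAATTAGGT, reached 11.04 ± 0.33 (SD, n = 64), 6.63-fold above it. On the HOXC11 array site 1, AGGTCGTAAAA, reached 13.33 ± 0.25 (SD, n = 96) and site 2, AGGTCGTTAAA, reached 13.36 ± 0.29 (SD, n = 96), with 7 and 5 of the 30 random sequences brighter, of which 3 and 2 carried no 5mC. The third brightest reference was POU6F1 site 1 on the HOXC11 array (13.23) and on the P53 array (11.93), and the p63 site on the POU6F1 array (8.51); these 3 values lay below the brightest random sequences.

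Taken as a set of 6, the references did not differ from the 30 random sequences by more than the spread among sequences. The difference of medians was 0.09 log2 units on the HOXC11 array (exact permutation p = 0.568), 0.15 on the P53 array (p = 0.224, exact) and 0.19 on the POU6F1 array (p = 0.0965, exact), and the set includes the sites of other proteins. The difference turned to -0.063 on unscaled intensities for HOXC11 and to -0.010 against the median of all sequences for P53. The random sequences with 5mC differed from the 16 without it on the HOXC11 array (median log2 signal 13.21 against 12.94, permutation p = 0.01) and on the POU6F1 array (8.18 against 8.38, permutation p = 0.00156). The groups were not matched for base content. Over the random sequences the signal followed the G and C content on both arrays (r = 0.650 and -0.915). The difference therefore cannot be credited to 5mC. The 95th percentile of the random sequences, above which a sequence counted as detected, was 13.50, 12.09 and 8.73 from all 30 and 13.50, 12.16 and 8.75 from those without 5mC on the HOXC11, P53 and POU6F1 arrays. Above the percentile from all 30 lay 3 of 522 sequences on the HOXC11 array, 194 on the P53 array and 112 on the POU6F1 array. These counts include the brightest random sequences, which lie above their own 95th percentile by construction. On the HOXC11 array the brightest of all sequences was a random one (13.541).

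**Figure D1:**
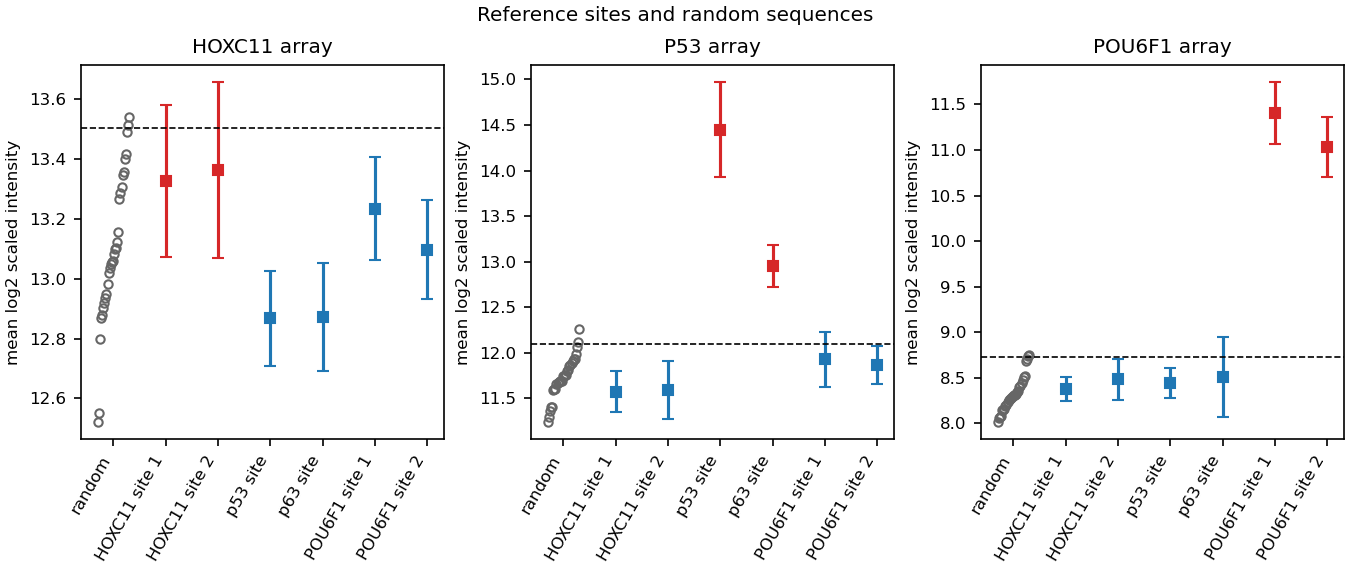
Mean log2 intensity (with SD over spots) of the 6 reference sites on each array, beside the 30 random sequences of that array. The p53 and p63 sites on the P53 array and both POU6F1 sites on the POU6F1 array lie above every random sequence; the HOXC11 sites on the HOXC11 array do not.

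Which bases of a site carry the binding was asked with every single-base substitution. On the P53 array 63 of the 81 tested substitutions were called, with 11 rises and 52 falls. Of 36 substitutions in the p53 site 33 lowered the signal and 3 were not called (T3A, C5T and G10A), and of 36 in the p63 site 19 lowered it and 2 raised it. The core cytosine at position 11 was the most sensitive base of both sites. In the p53 site the log2 change was -1.46 ± 0.10 (SE, n = 32 and 64, adjusted p = 2.82e-22) for C11A and -1.29 ± 0.11 (SE, adjusted p = 2.02e-18) for C11G. In the p63 site it was -1.03 ± 0.08 (SE, adjusted p = 1.39e-16) for C11A and the signal of A12C was 2.001-fold lower (adjusted p = 2.78e-36). The largest rise in an own site was T8G in the p63 site, 0.31 ± 0.09 (SE, adjusted p = 0.00232), which was not called on the even-ordered spots (0.22). In the sites of other proteins, whose references were not detected, 9 variants were bright enough to be tested; a rise in these 9, which make up most of the 11, was fixed by that rule. The largest gains were A9C in HOXC11 site 1 (0.58 ± 0.05), A11T in HOXC11 site 2 (0.57 ± 0.04) and G8C in POU6F1 site 1 (0.38 ± 0.05). The rise of G8C was not called on unscaled intensities (0.17). All 43 unmethylated sequences with the half-site pattern RRRCWWGYYY lay above the 95th percentile of the random sequences, with a median log2 signal of 13.82. Most of them are the p53 reference and its variants, and that reference was itself detected, so the count gives no independent support for the pattern.

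**Figure D2:**
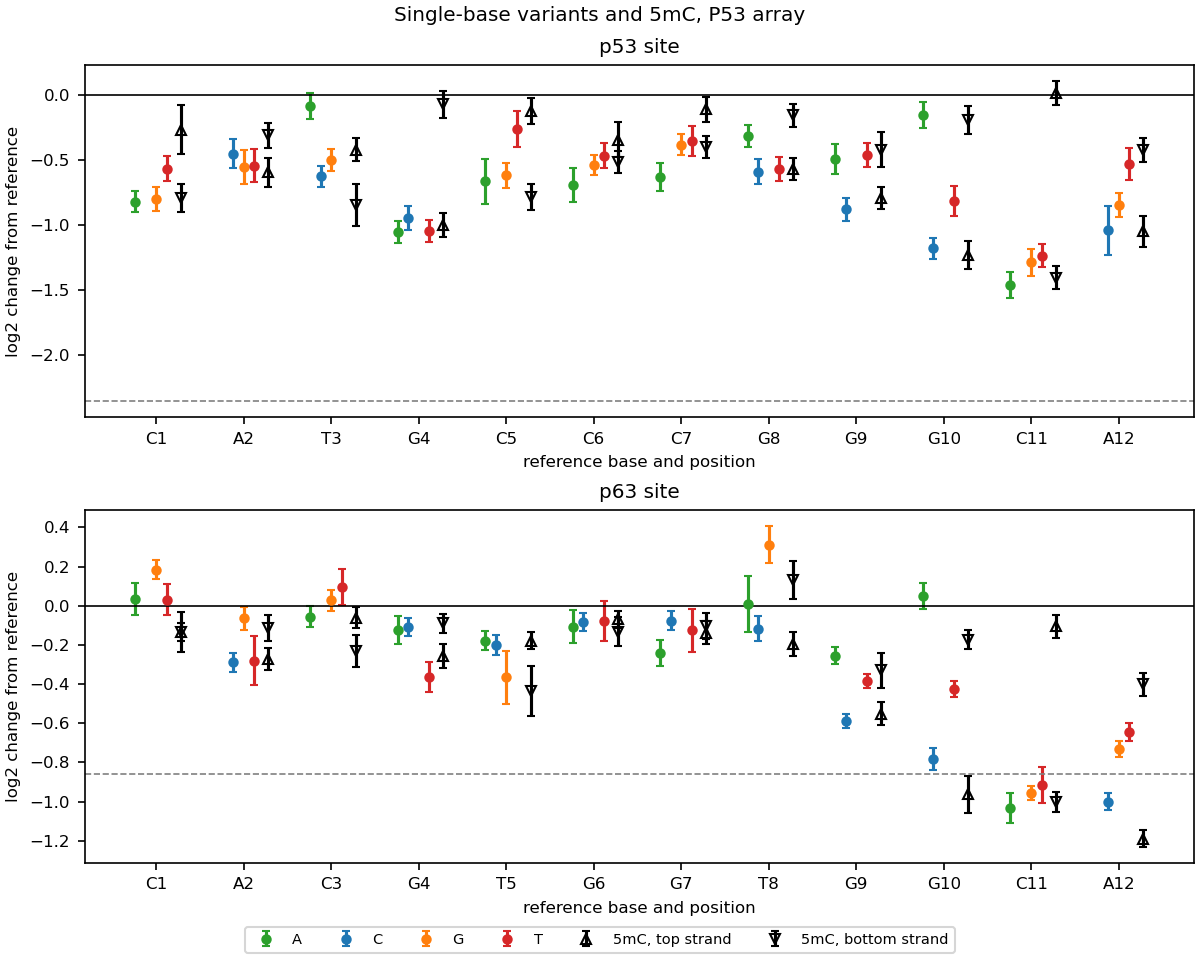
Log2 change of each substitution and of each 5mC from the reference on the P53 array (points, with SE) by position, for the p53 site and the p63 site. A 5mC that needs a substitution to make its cytosine or guanine is drawn with both changes together; the falls at position 11 are the deepest in the p53 site, to -1.46 for C11A.

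On the POU6F1 array 63 of 65 tested substitutions were called, with 11 rises and 52 falls, and the changes were larger. Substitution of the adenine at position 4 gave the deepest falls in both sites: the log2 change was -2.97 ± 0.05 (SE, n = 32 and 64, adjusted p = 5.81e-77) for A4C and -2.93 ± 0.05 (SE) for A4G in site 1, and -2.35 ± 0.05 (SE) for A4C and -2.51 ± 0.06 (SE) for A4G in site 2, which is a drop to within the range of the random sequences. In the opposite direction, G9A raised the signal by 2.56 ± 0.15 (SE, adjusted p = 5.45e-20) in site 2, a 5.89-fold change, and by 2.10 ± 0.21 (SE, adjusted p = 6.22e-12) in site 1, a 4.28-fold change. Outside its own sites, where the detection rule let only rises be tested, POU6F1 gained most from G6A in HOXC11 site 2, 1.29 ± 0.06 (SE, adjusted p = 6.7e-26), a substitution that creates TAATGA on the bottom strand, and from A11T in the same site, 0.55 ± 0.04 (SE). Of the unmethylated sequences with TAAT, 47 of 50 lay above the 95th percentile of the random sequences, as did all 14 with TAATTA and all 16 with TAATGA. These counts include the POU6F1 references and their variants, so they give no independent support for the motifs. No unmethylated sequence held an octamer or a CRE.

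On the HOXC11 array a single substitution could be tested and was called, A1G in site 2, with a log2 change of 0.17 ± 0.05 (SE, n = 32 and 96, adjusted p = 0.00113); its reference was not detected, so that only a rise could be tested, and it was not called on the even-ordered spots (0.12). Without the detection rule 30 of the 66 substitutions in the HOXC11 sites were called, 4 as rises and 26 as falls, the deepest being G6T in site 2 with -0.45 ± 0.04 (SE, adjusted p = 2.68e-18). In the sites of the other proteins 74 of 132 were then called, 46 as rises and 28 as falls.

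**Figure D3:**
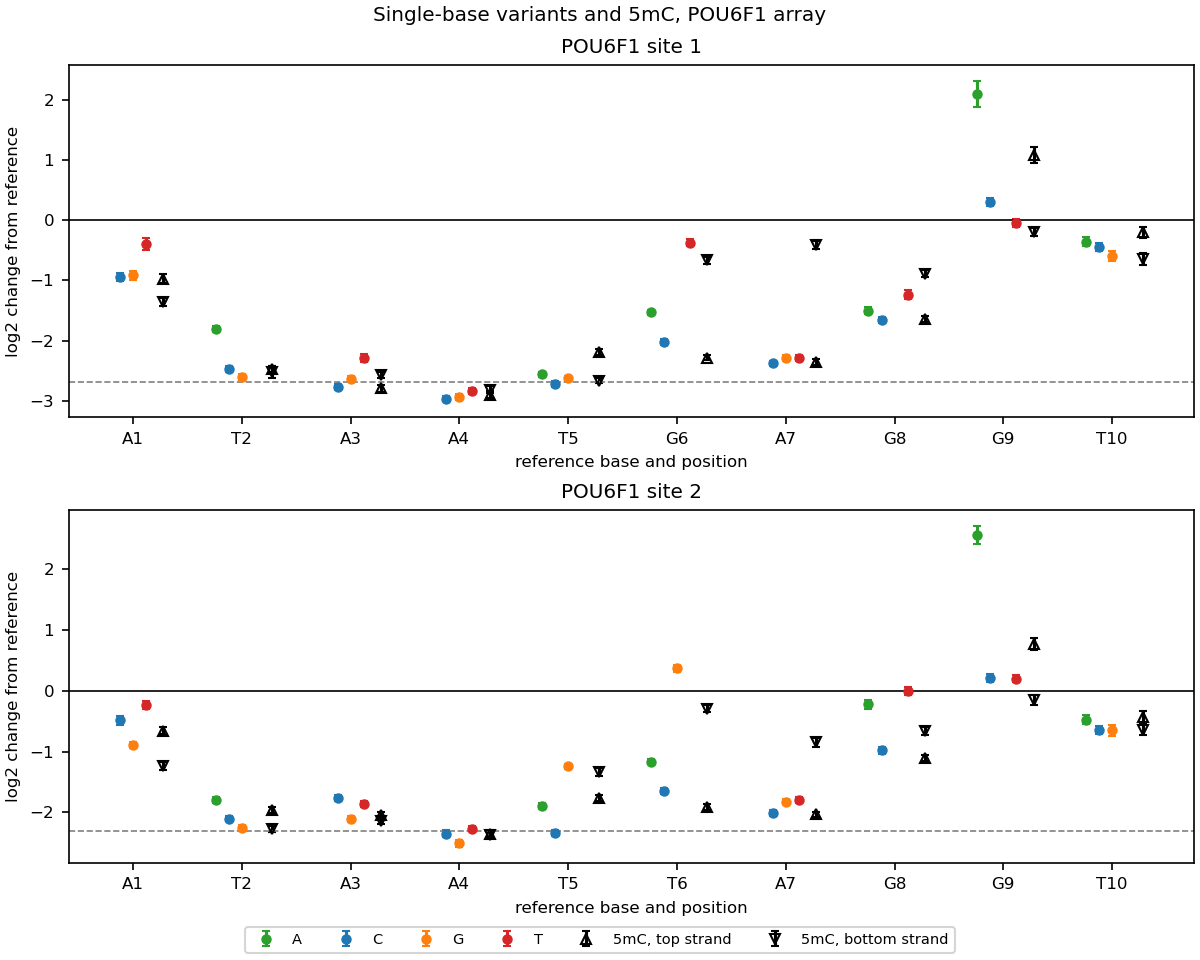
Log2 change of each substitution and of each 5mC from the reference on the POU6F1 array (points, with SE) by position, for both POU6F1 sites; the dashed line is the 95th percentile of the random sequences. G9A stands highest, at 2.10 in site 1 and 2.56 in site 2, and the changes at position 4 lie at or near the dashed line.

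Whether a single 5mC outside CpG alters binding was tested at each position of both strands. For P53, 6 of 30 contrasts were called and all 6 were falls. The count was 2 on odd-ordered spots, 1 on even-ordered spots and 3 on unscaled intensities. At a change of at least 1.5-fold it was 0, and without the detection rule 10. The median log2 change of the tested contrasts was -0.12 at CA, -0.15 at CC and -0.14 at CT. In the sites of other proteins 1 of 59 contrasts passed the rule. Without the rule 3 of these 59 were called, all falls. A general dimming by 5mC on this array was not tested apart from effects at a position. Methylation of the cytosine opposite position 9 lowered the signal of the p53 site by a log2 change of -0.42 ± 0.13 (SE, n = 32 and 64, adjusted p = 0.0246) and that of the p63 site by -0.33 ± 0.09 (SE, n = 32 and 64, adjusted p = 0.0122). These became -0.26 and -0.21 when outlying spots were left out. On unscaled intensities the p53 site's change (-0.34, adjusted p = 0.083) was no longer called, and neither was it on the odd-ordered or even-ordered spots alone (-0.55 and -0.29). Methylation opposite position 1 of the p63 variant C1G gave -0.32 ± 0.10 (SE, adjusted p = 0.0246), which fell to -0.11 without outlying spots and was then not called.

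At the core cytosines of the half-sites 5mC and substitution were compared, a choice made after the values were seen. In the p53 site every substitution at positions 1, 4 and 11 was a called fall. 5mC at position 11 changed the log2 signal by 0.01 (95% interval -0.17 to 0.20), and the methylated site was 1.25 ± 0.09 (SE) log2 units brighter than C11T. At the bottom-strand cytosine opposite position 4 the change was -0.07 (95% interval -0.28 to 0.14), and the methylated site was 0.98 ± 0.10 (SE) brighter than G4A. At position 1 the change was -0.26 (95% interval -0.65 to 0.12), and the difference from C1T, 0.30 ± 0.19 (SE), was not resolved. In the p63 site 5mC at position 11 gave -0.11 (95% interval -0.22 to 0.01), 0.81 ± 0.10 (SE) above C11T. At position 1 of that site, where C1T gave 0.03 and was not called, 5mC was a called fall of -0.14 (adjusted p = 0.0246). That fall lay near the median of the contrasts tested at CA on this array, -0.12. Opposite its position 4, within a CpG, 5mC gave -0.09 (95% interval -0.18 to 0.00376) and G4A -0.12, neither of them called.

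On the POU6F1 array 12 of 24 contrasts with a single 5mC outside CpG were called, 6 in each direction; in 1 of the rises, T5C of site 2, the unmethylated sequence was not detected. In the A7G variant, which weakens the site, 5mC opposite position 7 raised the signal by 1.87 ± 0.05 (SE, n = 32 and 32, adjusted p = 2.53e-38), or 3.67-fold, in site 1 and by 0.98 ± 0.07 (SE, n = 32 and 32, adjusted p = 6.97e-18), or 1.97-fold, in site 2. Methylation of the top strand raised the G9C variant of site 1 by 0.78 ± 0.14 (SE, adjusted p = 2.24e-06) and the T5C variant of site 2 by 0.57 ± 0.04 (SE, adjusted p = 9.12e-21). In the reference sites themselves the named 5mC contrasts were falls: opposite position 8 the change was -0.89 ± 0.06 (SE, adjusted p = 5.58e-24) in site 1 and -0.65 ± 0.07 (SE, adjusted p = 7.68e-15) in site 2, and opposite position 6 it was -0.67 ± 0.06 (SE, adjusted p = 8.03e-20) in site 1. Opposite position 9 it was -0.19 in site 1, which was called, and -0.15 in site 2, which was not. In the A3C variant of site 2 top-strand 5mC gave a change of -0.28 ± 0.04 (SE, adjusted p = 1.38e-10). On the HOXC11 array 0 contrasts passed the detection rule; without it 5 of 90 were called, all falls.

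Methylation of CpG on either or both strands gave 13 called contrasts of 82 tested on the P53 array, 8 rises and 5 falls, and 0 of them reached 1.5-fold. With both sequences detected there were 4 rises and 1 fall; the direction of the others was fixed by the detection rule. The count was 30 without outlying spots, with the median over the rest in place of the mean, and 22 with a spatial trend removed. It was 8 with detection at the 99th percentile or from the random sequences without 5mC. On unscaled intensities it was 7, with 6 rises and 1 fall. The CpG in the centre of the p53 site itself gave -0.11 ± 0.09 (SE) when methylated on the top strand, -0.16 ± 0.09 (SE) on the bottom strand and -0.04 ± 0.10 (SE) on both, and the CpG of the p63 site gave -0.12 ± 0.06 (SE) on both; none was called. Of the 4 named rises 3 were in sites of other proteins, where the unmethylated sequence was not detected, so that only a rise could be tested: 0.58 ± 0.10 (SE, n = 32 and 32, adjusted p = 1.49e-05) for top-strand methylation of A11C in HOXC11 site 2, 0.37 ± 0.09 (SE) for T10C in POU6F1 site 2 and 0.33 ± 0.05 (SE) for A11C in HOXC11 site 1. The second largest rise was in the p53 variant A12G, where bottom-strand methylation gave 0.42 ± 0.10 (SE, n = 64 and 64, adjusted p = 0.000204), which was not called on the even-ordered spots (0.37). Full methylation of the p53 variant C7G gave -0.35 ± 0.11 (SE, adjusted p = 0.0115) and was not called on unscaled intensities (-0.32) or on the odd-ordered or even-ordered spots alone (-0.45 and -0.25). The other named falls were -0.25 ± 0.03 (SE) and -0.17 ± 0.04 (SE) for full and bottom-strand methylation of T5C in POU6F1 site 1 and -0.15 ± 0.04 (SE) for top-strand methylation of A12G in the p63 site; on unscaled intensities the last 2 were not called (-0.19 and -0.17).

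Of 30 contrasts of CpG methylation tested on the POU6F1 array 14 were called, 11 as rises and 3 as falls. In 5 of the 11 the unmethylated sequence was not detected, so that only a rise could be tested; with both sequences detected there were 6 rises and 3 falls. The count was 8 on unscaled intensities, 22 without outlying spots and 1 at a change of at least 1.5-fold. In site 1 carrying G9C T10G, full methylation gave 0.59 ± 0.09 (SE, n = 32 and 32, adjusted p = 6.05e-08) and top-strand methylation 0.53 ± 0.09 (SE, adjusted p = 1.16e-06). The CpG of HOXC11 site 2, which POU6F1 bound at the level of the random sequences, gained 0.29 ± 0.03 (SE, n = 64 and 96, adjusted p = 1.17e-18) from bottom-strand methylation. Methylation of the bottom strand at A1G lowered the signal, by -0.44 ± 0.08 (SE, adjusted p = 3.84e-06) in site 1 and -0.34 ± 0.06 (SE, adjusted p = 1.08e-06) in site 2. The smallest named changes, 0.13 ± 0.03 (SE) for bottom-strand methylation of A7C and -0.13 ± 0.05 (SE) for top-strand methylation of G8C in site 2, were not called on unscaled intensities (0.11 and -0.14). On the HOXC11 array 0 of 1 tested contrasts was called by limma, 0 at an unadjusted p under 0.05; without the detection rule 8 of 176 were, all falls.

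Whether the effects of the 2 strands add was tested from all 4 methylation states of each CpG. For POU6F1, 3 of 10 departures were called, all negative. In site 1 carrying G6C A7G, bottom-strand methylation raised the signal by 0.51 ± 0.03 (SE), top-strand methylation by 0.01 ± 0.03 (SE) and full methylation by only 0.14 ± 0.03 (SE), a departure of -0.38 ± 0.05 (SE, adjusted p = 5.57e-13). In the T5C variant of site 1 top-strand methylation gave 0.53 ± 0.02 (SE), bottom-strand -0.15 ± 0.02 (SE) and full methylation 0.13 ± 0.02 (SE), a departure of -0.25 ± 0.03 (SE, adjusted p = 1.11e-12). The next largest, -0.18 ± 0.11 (SE, adjusted p = 0.254) for G9C T10G in site 2, was not called, but was without outlying spots (-0.27, adjusted p = 0.0126). The third called departure was that of HOXC11 site 2, -0.10 ± 0.04 (SE, adjusted p = 0.0486), chosen after its value was seen. Only its bottom-strand state (8.77) passed the detection level of 8.73. That state enters with a minus sign, so the rule favoured a negative departure, and without the rule it was not called. The other 2 called departures were still called without the rule, although their unmethylated sequences (8.71 and 8.69) were not detected either. For P53 limma called 0 of 26 departures, with 1 at an unadjusted p under 0.05. The largest were -0.25 ± 0.12 (SE) for A12G in the p63 site, 0.22 ± 0.14 (SE) for the p53 site and 0.22 ± 0.15 (SE) for A2G in the p63 site, each with an adjusted p of 0.707; the last turned to -0.025 without outlying spots.

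Effects of the same methylation contrast were compared between arrays by a test of the difference, wherever either array detected it. Outside CpG 12 of 24 contrasts differed between HOXC11 and POU6F1, 14 of 54 between P53 and POU6F1 and 3 of 30 between HOXC11 and P53. For CpG methylation the counts were 16 of 31, 19 of 99 and 12 of 83. Over both kinds, 28, 33 and 15 contrasts differed in these pairs, against 13, 18 and 8 on unscaled intensities and 37, 59 and 31 without outlying spots. On even-ordered spots 18, 28 and 9 differed, and 9 between HOXC11 and P53 with detection at the 99th percentile or from the random sequences without 5mC. Only 13 of these contrasts, all of CpG methylation on the P53 and POU6F1 arrays, were detected on both arrays of a pair, and 4 of the 13 differed. Detected here means that at least 1 sequence of the contrast passed the rule on each array, not always the same one. The other counts set an effect on 1 array against signal at the level of the random sequences on the other. Protein, tag, supplier and array change together in each comparison.

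5mC and thymine carry a methyl group at the same place of the base, and their effects at the same base pair were compared over positions, which are not independent replicates. On the P53 array Pearson's r was 0.459 over 59 positions (permutation p = 0.00021, adjusted p = 0.00042) and Spearman's rho 0.458 (permutation p = 0.00027). On the POU6F1 array r was 0.416 over 42 positions (permutation p = 0.00522, adjusted p = 0.00522) and rho 0.327 (permutation p = 0.0345). Without the 2 positions farthest from the median r was 0.563 and 0.403, and rho 0.509 (permutation p = 2e-05) and 0.269 (permutation p = 0.0935), so the rank relation of POU6F1 was then no longer past the threshold. On the P53 array r was 0.730 at 25 CpG positions (permutation p = 0.00012) and 0.021 at 34 positions outside CpG (permutation p = 0.906), a difference of 0.709 by permutation of the classes (p = 0.003), chosen after the values were seen; on the POU6F1 array r was 0.422 at 13 CpG positions (permutation p = 0.166) and 0.415 at 29 others (permutation p = 0.0222). Both effects are measured from the same unmethylated sequence, which alone can give a correlation; had every change been spot noise, the mean r would have been 0.406 and 0.332. The covariance, which keeps the size of the changes, was 0.0338 against 0.00365 from noise alone on the P53 array and 0.213 against 0.00147 on the POU6F1 array. With separate spots of the unmethylated sequence r was 0.364 (permutation p = 0.00452) and 0.384 (permutation p = 0.0108), and at the CpG positions of the P53 array 0.642 (permutation p = 0.00055). Separate spots remove shared spot noise only, since both effects still subtract the level of the same unmethylated sequence. With A or G in place of T, comparisons that were not planned, r was 0.113 and 0.148 on the P53 array and 0.082 and 0.216 on the POU6F1 array. For POU6F1 the relation rests on Pearson's r alone, and no relation of the ranks is claimed. The HOXC11 array had too few detected positions.

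**Figure D4:**
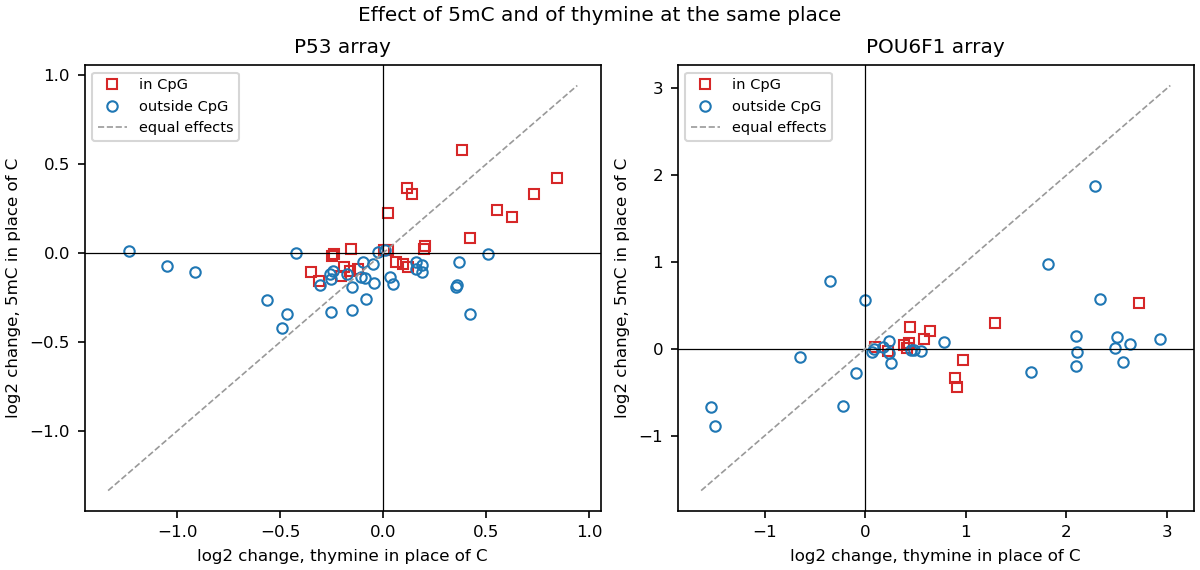
Log2 change given by 5mC against the log2 change given by thymine at the same base pair on the P53 array (59 positions) and the POU6F1 array (42 positions), with CpG and other positions marked. The highest 5mC effect on the POU6F1 array, 1.87, belongs to the A7G variant of site 1.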

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

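Of the tests weighed here, all but the mirrored comparison on unscaled intensities were chosen after the result was seen; the differences between proteins were planned, their counts on unscaled intensities were not.

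Methylation effects differed between arrays in all 3 pairs by the test of the difference. Outside CpG the counts were 3 for HOXC11 and P53, 12 for HOXC11 and POU6F1, and 14 for P53 and POU6F1; for CpG methylation they were 12, 16 and 19. The totals of 15, 28 and 33 became 8, 13 and 18 on unscaled intensities and 31, 37 and 59 without outlying spots. Between HOXC11 and P53 the largest differences were 0.37 ± 0.10 (SE, adjusted p = 0.00425) for 5mC opposite position 9 of the p63 site and -0.68 ± 0.11 (SE, adjusted p = 2.81e-06) for top-strand methylation of A11C in HOXC11 site 2. Between HOXC11 and POU6F1 they were -1.90 ± 0.07 (SE, adjusted p = 5.31e-52) for 5mC opposite position 7 of A7G in POU6F1 site 1 and -0.63 ± 0.10 (SE, adjusted p = 5.93e-08) for full methylation of G9C T10G in the same site. Between P53 and POU6F1 they were -1.90 ± 0.07 (SE, adjusted p = 4.06e-49) for the same A7G contrast and -0.65 ± 0.04 (SE, adjusted p = 3.21e-48) for top-strand methylation of T5C in POU6F1 site 1. Of these 6 contrasts only the last had a sequence that passed the rule on both arrays. In the others the value of the first-named array came from sequences no brighter than its detection level. On the P53 array only the unmethylated T5C sequence passed (12.135 against 12.094), and it lay below the level from random sequences without 5mC (12.156). On the POU6F1 array only the methylated one passed (9.21, against 8.69 unmethylated and a level of 8.73). The rule thus favoured a fall on the first and a rise on the second. Of 13 contrasts detected on both arrays, all of CpG methylation on the P53 and POU6F1 arrays, 4 differed. No biological explanation was tested, and protein cannot be separated from tag, supplier and array, since each protein had 1 array.

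The rise that 5mC gave in the A7G variants on the POU6F1 array was weighed against 3 explanations. A general brightening by 5mC is excluded, because the other 22 detected contrasts outside CpG had a median log2 change of -0.038 (quartiles -0.19 and 0.05, highest 0.78). Outlying spots are excluded, because without them the smaller of both rises was 1.04, and on unscaled intensities the rises were 1.93 and 0.97. That 5mC stands in for thymine at any position is excluded too: of 14 positions where thymine raised the signal by over 1 log2 unit, 5mC recovered at least 50% of that rise at 2, which were the A7G positions of site 1 (82.1%) and site 2 (53.7%). What stays open, as a hypothesis, is that the methyl group opposite position 7 itself may raise POU6F1 signal; both sequences of each contrast share array, protein and tag, and uracil in place of thymine there, not analysed here, would test it.

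Positions 3 to 12 of the p53 site are their own reverse complement, and the loop-side bases were more sensitive than their mirrored partners. Over 15 mirrored substitutions the loop-side change was lower by a mean of -0.20 log2 units (exact sign-flip p = 0.00854), and in 11 of them the loop side was lower. These substitutions come from 5 pairs of positions and share their reference, so they are not independent and the p-value overstates the evidence. The mean differences of the 5 pairs ran from -0.40 to -0.033. The local scaling of the authors does not account for the mean, which was -0.19 on unscaled intensities (exact sign-flip p = 0.0185, with the same limit). The sequence next to the site is excluded for the nearest bases by construction, as GACATGCCCGGGCATGTC, 18 base pairs around it, is its own reverse complement. The difference grew with the distance between mirrored positions, by a slope of -0.050 log2 units per base pair over 5 pairs of positions (exact permutation p = 0.0167, the smallest that 120 orders give), so position within the hairpin may be part of the unequal profile; loop, stem end and tail were not tested apart.

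Outside the hairpins, the PUC2 control probes, which the comparisons of the report do not use, were brighter than empty spots on each array. Over 85 probe spots of 5 kinds and 756 empty spots, the ratio of medians was 1.80 on the HOXC11 array, 12.4 on the P53 array and 1.94 on the POU6F1 array (permutation p = 2e-05 each, the smallest that the permutations give). On the first 2 arrays these ratios describe no kind of probe: 2 kinds stood at 1.51 and 1.52 and 3 kinds at 2.68 to 2.73 on the HOXC11 array, and 2 at 6.69 and 6.96 and 3 at 16.1 to 16.4 on the P53 array. On the POU6F1 array the 5 kinds lay between 1.87 and 1.99. The values in this paragraph are unscaled spot means, not the spot medians of the main results. Their median over all the probes together was 5329, 3189 and 402, against 10122, 4202 and 373 for the hairpins.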

How the results depend on the processing

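The alternatives on unscaled intensities, separate spots, own sites and random sequences without 5mC were chosen after seeing the data; the others were planned. No paired analysis was possible because each protein had 1 array. For the counts, correlations and reference comparisons, 179 alternative values kept their direction and side of the threshold, or for counts lay within 1.5 times the reported count; 42 counts moved further, 4 correlations were no longer past the threshold and 3 values reversed. Of 289 alternative values for 49 named contrasts, 264 kept direction and side, 22 lost the call, 1 gained it and 2 reversed. Except where stated, the cause was not tested.

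Without the detection rule more contrasts were tested, and the called substitutions became 104, 105 and 118 on the HOXC11, P53 and POU6F1 arrays. The called contrasts of 5mC outside CpG became 5 and 10 on the HOXC11 and P53 arrays, and those of CpG methylation 8 on the HOXC11 array. With the 99th percentile as threshold, CpG calls on the P53 array became 8 and differences between HOXC11 and P53 became 9; detection from the random sequences without 5mC also gave 8 and 9.

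Without outlying spots, CpG calls became 3, 30 and 22 on the HOXC11, P53 and POU6F1 arrays, called departures from additivity 2, 1 and 5, and differences between proteins 31 for HOXC11 and P53 and 59 for P53 and POU6F1. The departure of A2G in the p63 site became -0.025, and -0.13 on even-ordered spots.

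With fewer spots, odd-ordered spots gave 1 and 2 calls of 5mC outside CpG on the HOXC11 and P53 arrays and 1 CpG call on the HOXC11 array. Even-ordered spots gave 1 and 1 calls of 5mC outside CpG on these arrays, and 9 and 18 differences between HOXC11 and P53 and between HOXC11 and POU6F1. Removal of a spatial trend gave 22 CpG calls on the P53 array, and the spot mean column 2 substitutions on the HOXC11 array.

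A change of at least 1.5-fold, which excludes smaller changes by construction, left 0 and 27 substitutions on the HOXC11 and P53 arrays, 0 and 6 calls of 5mC outside CpG on the P53 and POU6F1 arrays, 0 and 1 CpG calls on these, and 0 departures on the POU6F1 array.

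On unscaled intensities, with a median spot SD of 0.89, 0.58 and 0.33 log2 units, 0 substitutions were called on the HOXC11 array, 3 contrasts of 5mC outside CpG on the P53 array, and 7 and 8 CpG contrasts on the P53 and POU6F1 arrays. Differences between proteins became 8 for HOXC11 and P53, 13 for HOXC11 and POU6F1 and 18 for P53 and POU6F1. The difference of the references from the random sequences became -0.063 on the HOXC11 array. Against the median of all sequences it became -0.010 on the P53 array.

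The correlation of 5mC with thymine on the P53 array became 0.021 outside CpG and 0.749 over the medians of 6 sites (exact permutation p = 0.297); on the POU6F1 array it was 0.422 at CpG positions, with 13 positions. With separate spots it was -0.022 outside CpG on the P53 array and 0.350 at CpG positions on the POU6F1 array. Site medians were not run on the POU6F1 array, which had too few sites. On the linear scale 1 departure was called on the P53 array.

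The level of the random sequences limits the HOXC11 array, where 3 of 522 sequences, random ones among them, passed the detection rule. Low signal over background understates falls on the POU6F1 array, because 75.7% of the spots lay above their local background.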

Other observations

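All tests in this part were chosen after the result was seen.

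HOXC11 sites were no brighter than many random sequences on the HOXC11 array. On unscaled intensities 10 of the 30 random sequences were still brighter than the dimmer HOXC11 site, so the pattern was not limited to scaled values. The median unscaled spot SD there was 0.89 log2 units, against an SD of 0.26 among the random sequences on scaled values. This ranking is therefore coarse and cannot exclude local scaling by the authors as the source. Guanine in the first strand is a candidate explanation for part of the signal. In the sites of other proteins, substitutions that add a guanine changed the log2 signal by a median 0.15 (n = 30). Those that remove one changed it by -0.0099 (n = 42), a difference of 0.16 (permutation p = 2e-05). Among the latter, G-to-C substitutions had a median of 0.059, a rise. Substitutions in a site share its reference, so the permutation p-values over substitutions treat dependent values as independent. Over the 30 random sequences the signal correlated with the guanine count (r = 0.757, permutation p = 1e-05, the smallest possible, rho 0.774). Without the 2 farthest sequences r was 0.750. The G and C content correlated with the HOXC11 signal as well (r = 0.650, adjusted p = 0.00026). Substitutions that raise it were brighter by 0.10 than those that lower it (permutation p = 0.00028). C-to-G substitutions, which keep that content, exceeded G-to-C substitutions by 0.15 (n = 8 and 14, exact permutation p = 0.003). The POU6F1 sites hold no top-strand cytosine, so every C-to-G substitution lay in the p53 or p63 site. Those references were dimmer (12.87 each) than those of the POU6F1 sites (13.23 and 13.10), which gave part of the G-to-C substitutions. The contrast is mixed with site and cannot exclude G and C content as the only cause. Whether substitutions within the posterior homeobox element of HOXC11 site 1, at positions 5 to 9, cost more signal than those outside it cannot be told apart from no effect: the difference of medians was -0.00036 (n = 15 and 18, permutation p = 1). The prediction had also taken a p of 0.05 or more as evidence against a contact; that clause was not used, because the substitutions in the element went in both directions and a missed p shows no equality.

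On the POU6F1 array the signal of the 30 random sequences fell with their G and C content (r = -0.915, permutation p = 1e-05, the smallest possible; rho -0.958, without the 2 farthest r = -0.919). On the HOXC11 array the relation was the opposite (r = 0.650), and on the P53 array no such relation was detected (r = -0.090, permutation p = 0.636). Of the 6 relations with base content computed, 3 had an adjusted p under 0.05 by Pearson's r.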
